A study of Rattus norvegicus with 24 samples.

How the data were processed

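The series measured transcript levels in the brains of male Wistar rats after a single intraperitoneal injection of MK-801 (dizocilpine), a channel blocker of the NMDA type of glutamate receptor, at 0.08 mg/kg (low dose) or 0.16 mg/kg (high dose), or of saline. Per the labels, 9 rats were used, 3 of them given saline, and brains were taken 40 min after injection and dissected into 6 regions: cortex, hippocampus, amygdala, hypothalamus, midbrain and ventral striatum. The sample labels give an age of 9 weeks and the design text 10 weeks. Total RNA was purified on silica columns and amplified and dye-labelled by linear amplification, per the labels' protocols. Each of the 24 arrays was a 2-colour hybridisation of RNA of treated rats against RNA of saline rats from the same region. Every combination of 6 regions and 2 doses was measured on 2 arrays of opposite dye. On replicate 1 the treated RNA carried Cy5, and on replicate 2 it carried Cy3. The labels state neither how many rats contributed to an extract nor whether both arrays of a pair held different extracts, so a pair was counted as 1 replicate. The p-values given here therefore measure only the spread between regions or between arrays, which may be technical, and not the spread between rats. The number of arrays limits the precision of every value.

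The scanner output held spot intensity in both channels, per the file headers, as mean signals on a linear scale with local background, made by Agilent Feature Extraction version 9.5.3.1 according to the submitters' processing notes and the file headers. The same files held log10 ratios of Cy5 over Cy3 and background-subtracted, dye-normalised signals, per the file headers. The value table deposited by the authors was log10 of treated over saline, rounded to 2 decimals, and 100% of its values lay within 0.01 of the log10 ratio computed from the scanner software's processed signals once the swapped arrays were turned. Its scale and direction were thus settled from the values. No further centring was seen: medians of its columns were -0.03 for replicate 1 of the high-dose amygdala, -0.02 for replicate 1 of the high-dose ventral striatum and hippocampus, 0.02 for replicate 2 of the hippocampus at both doses, and between -0.01 and 0.01 for the others. All columns of that table belonged to a sample, leaving 0 without one. Any filter applied before hybridisation data were exported is not given in the sources used here.

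Analysis started from the mean signals and local background medians. Background was corrected with normexp at an offset of 50, and log2 ratios were normalised within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). Outlier spots marked by the scanner software were left out, and saturated spots were kept. Ratios of swapped arrays were turned so that every value is treated over saline. Spots of 1 probe were averaged, and a gene with several probes was represented by the probe with the highest mean brightness over all arrays. Names were updated through a reference table of the GRCr8 assembly used only for names: of 43379 spots that were not controls, 12697 were named through their systematic accession, 126 through another accession, 5726 by a file symbol the table holds and 3732 by a synonym, and 21098 kept the name in the file. The 41012 probes gave 35526 features, 15610 of them with a gene symbol, and 28420 were tested in at least 1 region and dose. Probe coordinates are those printed in the files, which refer to the rn3 build. No genome or annotation of that build was used here, so exons and untranslated regions are not stated.

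Signal quality limits what can be seen. Median net signal per channel ranged from 47.3 to 357 intensity units over the arrays, and the share of spots well above background from 56.8% to 89.7%. Between 236 and 708 spots per array were marked as outliers and at most 8 were saturated. Spike-in controls gave slopes of 0.816 to 0.958 and correlations of 0.982 to 0.997 between observed and stated log ratios. Ratios of these controls were thus slightly compressed. How far ratios of genes were compressed after background correction with an offset, above all those of dim probes, was not measured. The median log2 ratio over genes lay between -0.0191 and 0.0169 on every array. Across genes, which are not independent replicates, the ratios of dye-swapped arrays correlated between -0.475 and -0.0895, with an SD of the dye effect over genes of 0.110 to 0.125. After removal of a mean dye effect per gene these correlations were -0.0861 to 0.424, and among genes whose mean exceeded 1.5-fold they were 0.539 to 0.974.

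Samples were grouped by region and dose from the labels. The main tests, the 26 gene lists, the alternatives other than scan day and the rule for naming genes were fixed before the data were examined, whereas the scan day alternatives, an interferon-stimulated list and most tests of explanations were chosen later. Within a region and dose there is 1 replicate and no test of the condition: a gene was called when both arrays showed at least 1.5-fold in the same direction and the gene was well above background in the treated or the saline channel on both. The number of genes beyond 1.5-fold in opposite directions is given beside it and counts disagreement between the 2 arrays. Dye bias adds to that number. A difference between extracts does not show in it if a pair holds the same extracts, so the number does not measure the error of the calls. Doses were compared within a region by the same rule, on differences between arrays of the same dye orientation. Across regions, the mean of each pair was 1 value, and limma (lmFit and eBayes with an intensity trend) tested whether the mean over 6 regions differed from 0, for each dose and for the high dose minus the low dose. A gene needed at least 5 region values and a signal well above background in at least 4 regions. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A secondary limma fit of all 24 arrays with 1 dye effect per gene compared the hybridised RNA samples, not the conditions.

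The 26 gene lists comprised immediate early and activity-regulated genes, glucocorticoid-responsive genes, heat shock and chaperone genes, glutamate receptor genes, GABA, dopamine and serotonin signalling genes, circadian clock genes, inflammatory genes, hypothalamic neuropeptide genes, markers of striatal, cortical, hippocampal, thalamic, midbrain dopamine and serotonin, and hypothalamic neurons, markers of oligodendrocytes, astrocytes, microglia, endothelial and mural cells, choroid plexus and ependyma, meninges and fibroblasts, blood cells, and pituitary and pineal, and cytosolic ribosomal protein and oxidative phosphorylation genes. Lists were tested across regions with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. A region value missing for a gene was replaced in these list tests by the mean of its other regions. Within a region, a list's median was placed among 10000 random lists of the same size matched on brightness in 20 bins, as a description of these arrays. The naming rule took, per region and dose, the 5 highest and 5 lowest called genes with a symbol, 3 and 3 between doses, the 10 highest and 10 lowest across regions among genes past the threshold with 1 sign in all 6, up to 4 called members of each list, and Fos, Arc, Egr1, Junb and Nr4a1 in every region. Results of 2 genes that this rule selected are not reported here.

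Where a probe was not well above background in 1 channel on both arrays, its change is given as a bound: the mean of the brighter channel against the higher of the dim probe's own signal and the lowest signal well above background, after loess and Aquantile normalisation. The software called a spot well above background when its net signal exceeded 13 background SDs, per the file headers. Slide and region coincided. Arrays were scanned on 3 days, the first holding hippocampus and hypothalamus, the second cortex and ventral striatum, and the third midbrain and amygdala. Alternatives were the scanner software's processed signals, the deposited table, median centring, an offset of 16, other filters on dim probes, the mean over probes, a 2-fold threshold, the array-level fit, leaving out each array or region, the slide or region as a random block, and scan day as a block or alone.

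The steps were tested on simulated arrays with changed genes of known size. For the high dose across regions (21796 genes) the fit recovered 71.6% of genes changed by 0.2 and 100% at 0.4 and 0.8, with 9 unchanged genes called, 4.74% of all calls. For the difference between doses (20649 genes) it recovered 37.3%, 97% and 100%, with 4.29% of calls false. With no changed gene at the low dose (22927 genes) it made 0 calls. For the high-dose cortex (25335 genes) the rule of size recovered 0% at 0.2, 0% at 0.4 and 78.5% at 0.8 with 1 unchanged gene called, and the array-level fit 8.96%, 68.7% and 100% with 8 unchanged genes called. There 10 genes exceeded 1.5-fold in opposite directions. With 1 of 26 lists shifted by 0.1, camera called 0 unchanged lists and fry 2. Simulated noise was independent between genes and arrays, and the dye effect was equal on both arrays of a pair. Shared saline RNA and differences between rats or dissections were not simulated, so these false calls do not cover them. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.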

Results

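Transcript levels were measured in 6 brain regions of rats killed 40 min after MK-801, an NMDA receptor channel blocker, on 24 arrays, with 2 arrays of opposite dye for each of the 12 combinations of region and dose. All values are log2 ratios of treated over saline RNA unless stated otherwise. A value of a single region is given with the SD of its 2 arrays, and a value across regions with the SE of the limma fit over 6 regions. As the 2 arrays are of opposite dye, that SD includes the gene's dye effect, also the part that cancels in the mean. The design addresses which transcripts change within minutes of MK-801 in each region, and whether the low dose (0.08 mg/kg) and the high dose (0.16 mg/kg) differ.

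In the saline channels, each of 5 lists of region markers was highest in its own region; no list was set for the amygdala. Striatal projection neuron markers were 3.88 log2 units higher in the ventral striatum than in the other 5 regions (median of 17 genes, 17 higher), and midbrain dopamine and serotonin neuron markers were 3.84 units higher in the midbrain (11 of 11). Cortical glutamatergic markers stood 1.51 units higher in the cortex (11 of 12) and hippocampal markers 1.48 units higher in the hippocampus (8 of 10). Hypothalamic markers differed least, at 0.07 units (7 of 11), although Pmch, the precursor of melanin-concentrating hormone, was 4.51 units higher in the hypothalamus. A list of hypothalamic neuropeptides, not counted among the 5, was not highest there (-0.06, 12 of 25 genes higher) but in the amygdala (0.05, 15 of 25). Thalamic neuron markers, also not counted among the 5, stood 2.31 units higher in the hypothalamus than in the other 5 regions (12 of 12). The hypothalamic list alone thus does not settle what that piece held. Slide and region cannot be told apart in these levels.

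At the high dose, several early response genes were among the most increased across regions. Ccn1, listed as Cyr61 and encoding a secreted matrix protein, rose by 2.68 ± 0.38 (SE, n = 6 regions, limma adjusted p = 0.00234), from 0.65 in the midbrain to 4.16 in the cortex. Its other probe rose by 1.29. Apold1, an early response gene of endothelial cells, rose by 1.93 ± 0.22 (limma adjusted p = 0.000445). Also increased were the antiproliferative gene Btg2 (1.29 ± 0.16), the zinc finger factors Klf4 (1.12 ± 0.13) and Klf2 (0.83 ± 0.09), the MAP kinase phosphatase Dusp1 (1.09 ± 0.10), Depp1 (0.95 ± 0.13) and Ier2 (0.78 ± 0.11). Sycp3l2 was higher too. Its exact size is not given, as its saline signal was well above background in 1 of 6 regions. Abcg2, an efflux transporter of the blood-brain barrier, rose by a nearly constant 0.69 ± 0.04 (limma adjusted p = 3.06e-06; 0.54 to 0.83). The Ccn1 probe lies on chromosome 2 (243811128 to 243811187, rn3), that of Apold1 on chromosome 4 (172152432 to 172152491) and that of Dusp1 on chromosome 10 (16945391 to 16945710).

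The most decreased transcript was Galnt16, which encodes an enzyme that starts mucin-type O-glycosylation. Its ratio was -1.98 ± 0.06 (limma adjusted p = 1.15e-08), between -2.24 and -1.78 in every region (chromosome 6, 104363509 to 104367590, rn3). P3h3, a collagen prolyl hydroxylase, stood at -0.74 ± 0.04 (limma adjusted p = 1.84e-06) and its other probe at -0.04. At the low dose P3h3 was instead higher, at 0.49 ± 0.04 (limma adjusted p = 3.88e-05), with its other probe at 0.01. Another 5 of the 10 most decreased genes are known to be induced by interferon: Irf7 (-0.59 ± 0.03), Isg15 (-0.54 ± 0.05), Oas1a (-0.46 ± 0.05), Bst2 (-0.46 ± 0.07) and Rtp4 (-0.46 ± 0.06). Completing the list were the transcriptional repressor Trps1 (-0.51 ± 0.04, its 2 other probes averaging 0.02), the amylase Amy1 (-0.45 ± 0.05, with treated RNA well above background in 5 regions) and Dusp19 (-0.44 ± 0.03). All of these genes had 1 sign in 6 of 6 regions. In total, 507 of 21796 genes passed the threshold (272 up and 235 down), 463 of them with 1 sign in all 6 regions, against 2679 at an unadjusted p under 0.05. Most changes were small, with a median size of 0.194 among called genes and 26 beyond 1.5-fold. The count was 304 without the cortex, 321 without the ventral striatum, 335 without the amygdala and 287 with median centring (131 up, 156 down). It was 447 with scan day as a block, and 108, 410 and 198 within scan days 1, 2 and 3 alone.

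Gene lists at the high dose gave 3 groups that were higher and 1 that was lower. Of 45 measured immediate early genes, 14 rose and 1 fell (19 and 5 adjusted over the list alone), with a median of 0.06 and a camera adjusted p of 7.92e-07, or adjusted p = 0.467 with an estimated correlation. Besides the genes above, Atf3 rose by 1.46 ± 0.29, Sik1 by 0.59, Fos by 0.55 ± 0.08 (limma adjusted p = 0.0022), Gadd45g by 0.55 and Junb by 0.34, whereas the neurotrophin Bdnf fell by 0.15. Of 17 glucocorticoid-responsive genes, 10 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.15; camera adjusted p = 7.17e-19, or adjusted p = 0.132 with an estimated correlation). These included the kinase Sgk1 (0.63 ± 0.05), Map3k6 (0.39), the leucine zipper gene Tsc22d3 (0.34) and the steroid receptor chaperone Fkbp5 (0.19). Blood cell markers rose in 4 of 6 cases (5 adjusted over the list alone; median 0.24; camera adjusted p = 1.14e-07, or adjusted p = 0.135 with an estimated correlation), among them Hbb at 0.33, Pf4 at 0.32 and Alas2 at 0.30. The 20 GABA signalling genes had a median of -0.04 (camera adjusted p = 0.0389, or adjusted p = 0.261 with an estimated correlation), with 0 genes past the threshold, over the list alone too. That list's p was 0.116 with the scanner software's processed signals, 0.0636 with median centring, 0.0526 at an offset of 16 and 0.12 in the deposited table. With scan day as a block the adjusted p was 3.99e-07 for immediate early, 2.36e-18 for glucocorticoid-responsive, 9.07e-08 for blood and 0.018 for GABA genes. Within the 3 scan days the medians of the glucocorticoid-responsive list were 0.127, 0.171 and 0.17, and those of blood markers 0.21, 0.196 and 0.242. Those of the immediate early list were 0.065, 0.0885 and 0.0397, and those of GABA genes -0.0366, -0.0225 and -0.0303.

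The other 22 lists did not pass at the high dose. The camera adjusted p was 0.132 for serotonin signalling genes and oligodendrocyte markers, 0.135 for inflammatory genes and microglia markers, and 0.22 for glutamate receptors, hypothalamic neuropeptides, hypothalamic region markers and oxidative phosphorylation genes. It was 0.406 for pituitary and pineal markers, 0.5 for astrocyte markers and for choroid plexus and ependymal markers, 0.637 for ribosomal protein genes, and 0.661 for heat shock genes and for striatal, hippocampal and thalamic markers. Values were 0.672 for clock genes, 0.714 for dopamine signalling genes and for endothelial and mural markers, 0.814 for cortical markers, and 0.85 for midbrain neuron markers and meningeal markers. Median, mean and test differed in sign in the midbrain neuron list (median 0.02, mean -0.00328, test upward) and in the meningeal list (median -0.02, mean -0.00162, test upward). Single members passed the threshold in lists that did not, among them the astrocyte transcription factor Sox9 (-0.34), the complement gene C3 (0.25), the VEGF receptor Kdr (-0.18), Hspb1 (0.22), Aspa (0.31) and Grm2 (-0.13).

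**Figure D1:**
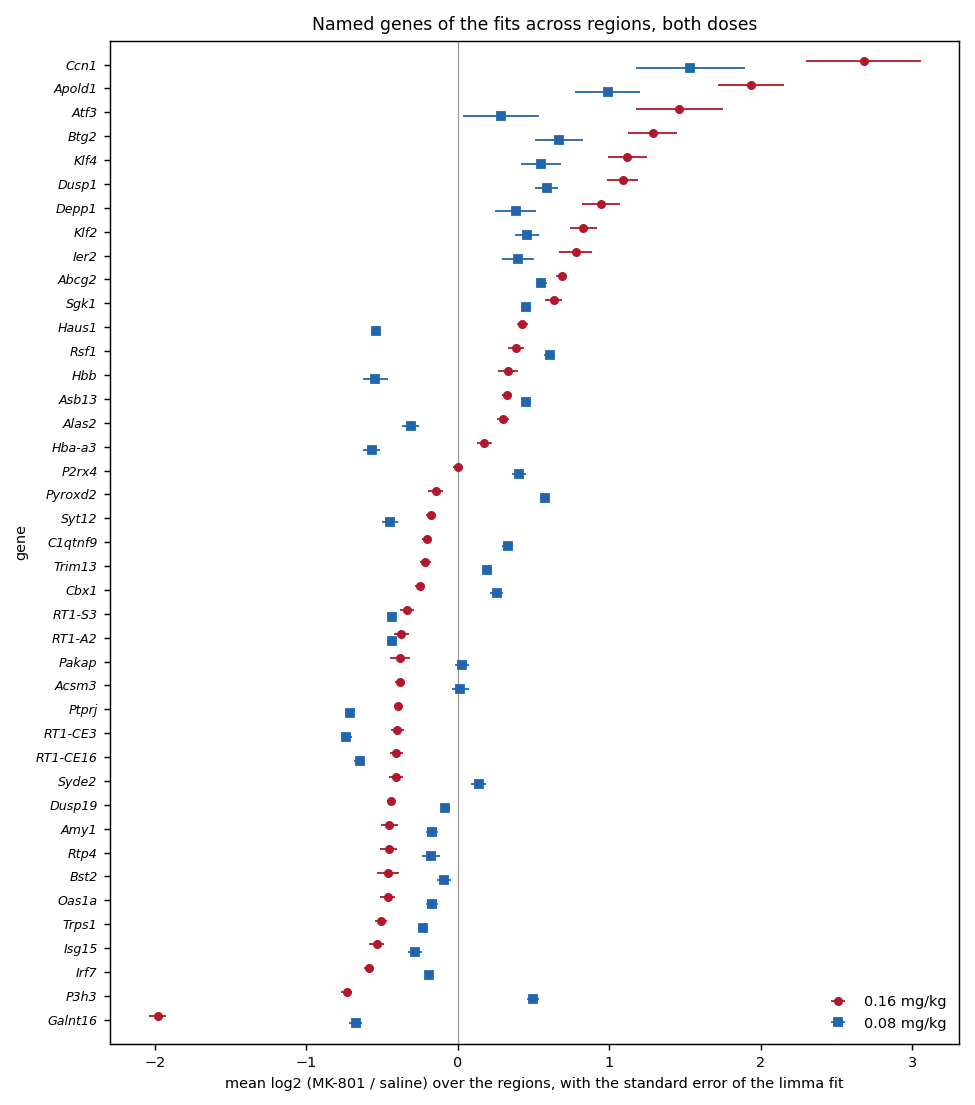
Mean log2 ratio of MK-801 over saline across 6 brain regions (horizontal axis, log2 units) for the genes named across regions (vertical axis), with points for the high and the low dose and bars for the SE of the limma fit. Ccn1 lies at 2.68 and Galnt16 at -1.98 at the high dose, against 1.53 and -0.68 at the low dose; Sycp3l2 is not drawn because its saline signal was near background.

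At the low dose, single early response genes rose again, although their list did not pass. Moreover, 4 class I histocompatibility genes were among the most decreased. Apold1 rose by 0.99 ± 0.22 (limma adjusted p = 0.0291), Btg2 by 0.67 ± 0.16 (limma adjusted p = 0.0433) and Dusp1 by 0.59 ± 0.07 (limma adjusted p = 0.000834), each in 6 of 6 regions. The call of Btg2 was lost with the processed signals, in the deposited table and with the mean over probes, at 0.69, 0.68 and 0.67. Klf2 (0.46 ± 0.08), the transporter Abcg2 (0.55 ± 0.04) and the kinase Sgk1 (0.45 ± 0.03) rose as well, together with the chromatin remodelling factor Rsf1 (0.61 ± 0.04), Pyroxd2 (0.57 ± 0.03) and Asb13 (0.45 ± 0.03). Decreases included class I histocompatibility genes, which present peptides to T cells: RT1-CE3 (-0.74 ± 0.04, limma adjusted p = 7.74e-07), RT1-CE16 (-0.65 ± 0.03), RT1-A2 (-0.44 ± 0.03, its other probe at 0.05) and RT1-S3 (-0.44 ± 0.03). The receptor phosphatase Ptprj stood at -0.71 ± 0.03 (limma adjusted p = 1.96e-07; chromosome 3, 74690369 to 74690428, rn3), with its other probe at -0.23. Galnt16 stood at -0.68 ± 0.04. Also lower were the haemoglobin genes Hba-a3 (-0.57 ± 0.05) and Hbb (-0.54 ± 0.08), the spindle assembly gene Haus1 (-0.54 ± 0.03, its other probe at 0.30) and the synaptotagmin Syt12 (-0.45 ± 0.05). Class I genes resemble each other in sequence, so their probes may cross-hybridise.

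Of 22927 genes tested at the low dose, 617 passed the threshold (309 up, 308 down), 563 with 1 sign in all 6 regions, against 3056 at an unadjusted p under 0.05. Their median size was 0.18, and 20 exceeded 1.5-fold. The count was 388 without the ventral striatum and 408 without the cortex. It was 423 with scan day as a block, and 274, 141 and 73 within scan days 1, 2 and 3.

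Among the lists, 3 were higher and 3 lower at the low dose. Glucocorticoid-responsive genes rose in 10 of 17 cases and fell in 0 (11 and 0 adjusted over the list alone; median 0.15; camera adjusted p = 1.16e-12, or adjusted p = 0.0119 with an estimated correlation), including Map3k6 at 0.27 and Tsc22d3 at 0.23. Of 16 oligodendrocyte and myelin markers, 2 rose, Aspa at 0.26 and Mag at 0.13 (9 up and 1 down adjusted over the list alone; median 0.08; camera adjusted p = 1.33e-05, or adjusted p = 0.431 with an estimated correlation). Of 16 microglia markers, 5 rose, over the list alone too, led by C1qc and Laptm5 at 0.22 and the purinergic receptor P2ry12 at 0.17 (median 0.05; camera adjusted p = 3.69e-05, or adjusted p = 0.431 with an estimated correlation). Meningeal and fibroblast markers were lower (median -0.25 over 13 genes, 1 down, 6 adjusted over the list alone; camera adjusted p = 4.26e-06, or adjusted p = 0.547 with an estimated correlation), and blood cell markers fell in 4 of 8 cases, over the list alone too (median -0.20; camera adjusted p = 0.000377, or adjusted p = 0.431 with an estimated correlation). Region medians of the meningeal markers were -0.95 in the cortex, -0.51 in the hippocampus, -0.26 in the midbrain and -0.02 in the amygdala, but 0.04 in the ventral striatum and 0.10 in the hypothalamus. Heat shock genes had a median of -0.04 over 17 genes (2 down, 3 adjusted over the list alone; camera adjusted p = 0.00723, or adjusted p = 0.431 with an estimated correlation), with Hspa1a at -0.34 and Hspb1 at -0.20. With scan day as a block these adjusted p were, in the same order, 5.13e-13, 7.99e-06, 9.13e-05, 2.22e-06, 0.00114 and 0.00821. Scan day medians were 0.169, 0.124 and 0.118 for glucocorticoid-responsive genes and -0.2, -0.459 and -0.132 for meningeal markers. They were 0.0401, 0.0871 and 0.143 for oligodendrocyte, 0.0217, 0.0539 and 0.0599 for microglia, -0.208, -0.221 and -0.184 for blood, and -0.0292, -0.0207 and -0.0316 for heat shock genes.

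The immediate early list as a whole did not pass at the low dose (camera adjusted p = 0.46, median 0.01). Of its 47 members 6 rose and 5 fell (10 and 8 adjusted over the list alone). Ccn1 rose by 1.53 ± 0.36 (limma adjusted p = 0.0428; positive in 5 of 6 regions), Gadd45g by 0.31 and Errfi1 by 0.22. The activity-regulated transcription factors Egr2 (-0.41 ± 0.05, limma adjusted p = 0.000638; treated RNA well above background in 4 of 6 regions), Egr1 (-0.26 ± 0.04, limma adjusted p = 0.00397), Nr4a3 (-0.25) and Egr4 (-0.23) fell, as did Bdnf at -0.15. No other list passed, the lowest camera adjusted p being 0.0909 for choroid plexus markers and the highest 0.997 for inflammatory genes. Median and test differed in sign in the dopamine signalling (0.01, mean -0.02) and striatal lists (0.01, mean -0.00152), and mean and test in the inflammatory list (median -0.01, mean 0.01).

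Set against each other within regions, the doses differed in early response, haemoglobin and other genes. The high dose exceeded the low dose for Atf3, a stress-inducible transcription factor, by 1.18 ± 0.16 (n = 6 regions, limma adjusted p = 0.000861), for Ccn1 by 1.14 ± 0.13, for Apold1 by 0.94 ± 0.09, for Btg2 by 0.62 ± 0.09, for Depp1 by 0.56 ± 0.08 and for Dusp1 by 0.50 ± 0.06. Haus1 was higher by 0.97 ± 0.04 (limma adjusted p = 8.6e-09), being 0.43 above saline at the high dose and -0.54 at the low dose. Its other probe went the opposite way, at -0.16 and 0.30. Hbb (0.88 ± 0.07), Hba-a3 (0.74 ± 0.05) and the erythroid haem synthesis gene Alas2 (0.61 ± 0.04) also differed. Lower at the high dose were Galnt16 (-1.31 ± 0.07, limma adjusted p = 7.42e-08), Pyroxd2 (-0.72 ± 0.04), Syde2 (-0.55 ± 0.08), C1qtnf9 (-0.53 ± 0.04), the heterochromatin protein Cbx1 (-0.51 ± 0.04), Pakap (-0.41 ± 0.06), Trim13 (-0.41 ± 0.04), the ATP-gated channel P2rx4 (-0.40 ± 0.04) and Acsm3 (-0.40 ± 0.05). Cbx1 stood at -0.25 at the high and 0.26 at the low dose and its other probe at -0.05 and -0.01. All named here had 1 sign in 6 of 6 regions. The threshold was passed by 386 of 20649 genes (222 higher, 164 lower at the high dose), 334 of them with 1 sign in 6 regions, against 2365 at an unadjusted p under 0.05. Median centring gave 152. Scan day as a block gave 350, and scan days alone 56, 245 and 57.

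Of 44 immediate early genes, 17 were higher at the high than at the low dose and 0 lower (23 and 0 adjusted over the list alone; median 0.10; camera adjusted p = 1.09e-14, or adjusted p = 0.23 with an estimated correlation). Klf4 differed by 0.65, Fos by 0.50, Ier2 by 0.43, Sik1 by 0.41 and Jun by 0.32. Glucocorticoid-responsive genes differed little (median 0.02 over 16 genes, 2 higher, 5 adjusted over the list alone; camera adjusted p = 0.0124, or adjusted p = 0.591 with an estimated correlation), and median centring ended the call at 0.279. Blood cell markers were higher in 5 of 6 cases, over the list alone too (median 0.50; camera adjusted p = 1.32e-06, or adjusted p = 0.23 with an estimated correlation), and meningeal markers had a median of 0.24 over 13 genes with 0 past the threshold and 4 adjusted over the list alone (camera adjusted p = 1.44e-06, or adjusted p = 0.591 with an estimated correlation). Microglia markers were lower in 5 cases and higher in 1 of 15 (5 and 2 adjusted over the list alone; median -0.04; camera adjusted p = 0.0285, or adjusted p = 0.591 with an estimated correlation), with P2ry12 at -0.23. Oligodendrocyte markers had a median of -0.06 over 13 genes, with Mal at -0.19 the single member past the threshold, over the list alone too (camera adjusted p = 0.0223, or adjusted p = 0.808 with an estimated correlation). The blocked adjusted p were 4e-13 for immediate early, 0.00887 for glucocorticoid-responsive and oligodendrocyte, 1.7e-05 for blood, 2.91e-07 for meningeal and 0.0363 for microglia lists. Within scan days, immediate early medians were 0.0718, 0.128 and 0.125 and blood medians 0.492, 0.577 and 0.489. Meningeal medians were -0.134, 0.437 and 0.443, so that list differed in direction on scan day 1. Glucocorticoid-responsive medians were -0.00135, 0.0623 and 0.0483, oligodendrocyte medians -0.0838, 0.023 and -0.0963, and microglia medians -0.0747, -0.0434 and -0.0459. Among lists that did not pass, median and test differed in sign for heat shock (-0.00942, mean 0.06, test upward), serotonin (-0.02, mean -0.01, test upward), GABA (0.01, mean 0.000671, test downward), clock (0.00247, mean -0.01, test downward) and pituitary genes (0.02, mean -0.01, test downward), and mean and test for neuropeptide (-0.00653, median 0.00393, test upward) and ribosomal genes (-0.00366, median 0.01, test upward).

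Both doses shared part of their called genes. Of 21312 genes tested at both, 98 were up and 85 down at both doses, where independent lists would share 3.72 and 3.25, and 13 were up at the high and down at the low dose and 12 the reverse (3.71 and 3.26 for independent lists). Both doses may have been set against the same saline RNA, so independent lists are not the overlap expected without a response. Part or all of the excess may come from shared controls. Across genes, which are not independent replicates, the correlation of the doses within a region was 0.441 in the cortex and ventral striatum, 0.412 in the hippocampus, 0.378 in the hypothalamus, 0.347 in the amygdala and 0.34 in the midbrain, with Spearman values of 0.269 to 0.364. Unchanged groups simulated against shared saline RNA gave 0.498 to 0.505, above the observed value in every region. That value follows from the shared denominator and hardly varied between regions. Noise of single arrays, which the doses do not share, would lower it by an amount that was not measured. The comparison therefore cannot tell whether the doses agree less than shared saline alone would give, and the covariances below have the same limit. The covariance differed from the simulated one by 0.00118 in the cortex, 4.71e-05 in the ventral striatum, -0.00038 in the hippocampus, -0.000713 in the hypothalamus, -0.000794 in the midbrain and -0.0016 in the amygdala. Calls shared by both doses were 17 up and 2 down in the cortex, 5 and 0 in the ventral striatum, 5 and 3 in the amygdala, 2 and 7 in the hippocampus, 1 and 5 in the hypothalamus, and 1 and 4 in the midbrain, against at most 0.0278 for independent lists. Shared saline RNA can raise these counts too, so they do not show a shared response.

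Within single regions, 362 calls were made by the rule of size, involving 180 different genes, while 129 gene values exceeded 1.5-fold in opposite directions on the arrays of a pair. At the high dose Ccn1 was called up in 6 regions, Apold1, Btg2 and Dusp1 in 5, and Atf3, Abcg2, Depp1, Klf2 and Klf4 in 4, and Galnt16 was called down in 6 and P3h3 in 4. Low-dose calls of Ccn1 were made in 4 regions upward and of Apold1 in 3, and Ptprj was called down in 5, RT1-CE3 in 4 and Galnt16 in 3. Fos was called in the high-dose cortex (0.90 ± 0.25) and amygdala (0.78 ± 0.08), and Nr4a1, an orphan nuclear receptor, in the high-dose cortex (0.84 ± 0.17) and hypothalamus (0.85 ± 0.03). Nr4a1 had no value in the high-dose amygdala and midbrain because a spot was marked as an outlier. Arc, Egr1 and Junb were not called in any region at either dose: the highest means were 0.28 ± 0.16 for Arc in the cortex and, in the hypothalamus, 0.03 ± 0.12 for Egr1 and 0.69 ± 0.26 for Junb, all at the high dose.

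**Figure D2:**
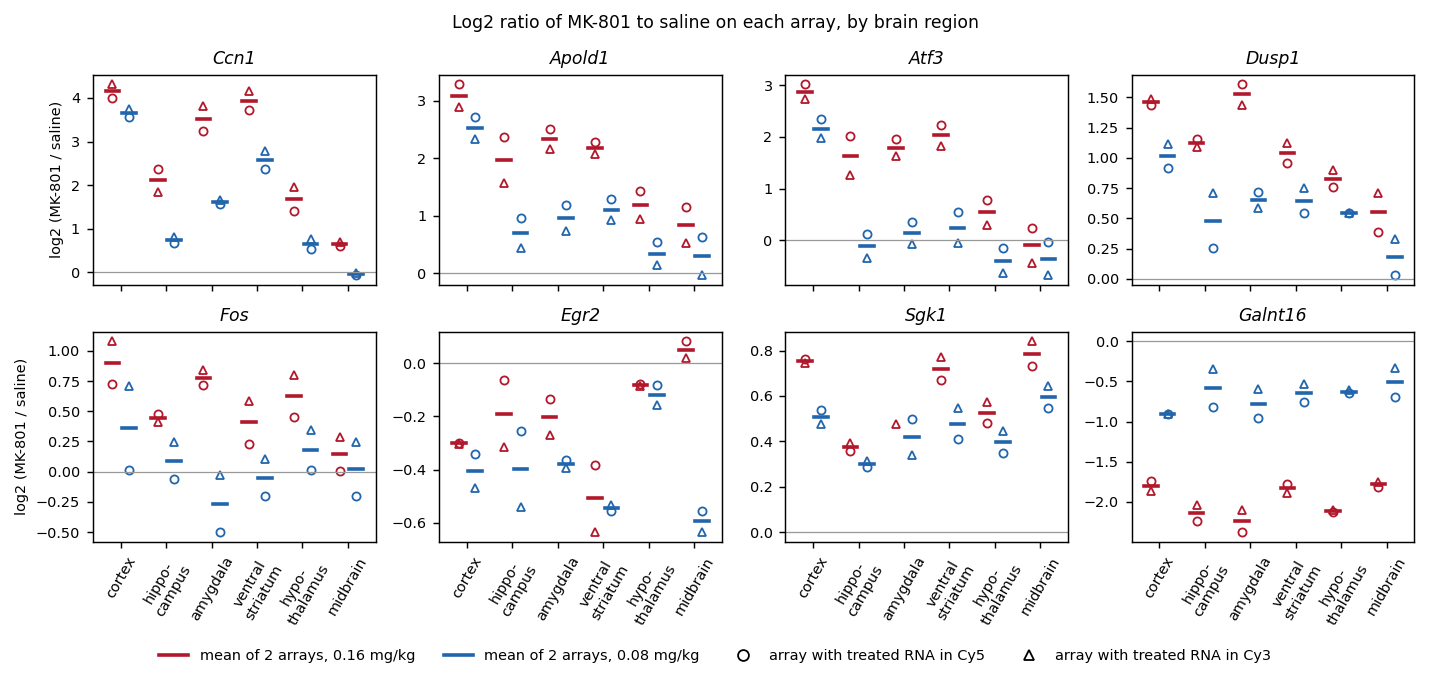
Log2 ratio of MK-801 over saline (vertical axis) of 8 genes on each array, by region and dose (horizontal axis); circles are arrays with treated RNA in Cy5, triangles those with treated RNA in Cy3, and bars the mean of 2 arrays. Ccn1 spans 0.65 to 4.16 at the high dose, and Galnt16 lies between -2.24 and -1.78 in all regions at that dose.

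In the cerebral cortex the high dose raised Ccn1 by 4.16 ± 0.22 (n = 2 arrays), Apold1 by 3.08 ± 0.29, Atf3 by 2.87 ± 0.21, Btg2 by 2.07 ± 0.25 and Klf4 by 1.78 ± 0.26. The monocyte chemokine Ccl2 rose by 1.63 ± 0.06 and the chaperone Hspa1a by 0.79. Galnt16 (-1.80 ± 0.08), the endothelial transcription factor Sox18 (-0.86 ± 0.03) and P3h3 (-0.76 ± 0.21, whose probes disagree in sign) were lower. At the low dose Ccn1 (3.66 ± 0.14), Apold1 (2.53 ± 0.27), Atf3 (2.16 ± 0.27), Btg2 (1.79 ± 0.03) and Depp1 (1.31 ± 0.10) were higher. The decreases were of another kind: the small proteoglycan Ogn (-1.36 ± 0.20), Coch (-1.33 ± 0.06), the cardiac troponin Tnnt2 (-1.29 ± 0.11), the prostaglandin D synthase Ptgds (-1.24 ± 0.11), E-cadherin Cdh1 (-1.19 ± 0.23), the collagen Col1a2 (-1.16 ± 0.16), Kcnj13 (-1.14 ± 0.01), Igf2 (-1.07 ± 0.31) and Cd74 (-0.73 ± 0.09). Meningeal and fibroblast markers had a median of -0.95 over 14 genes at the low dose, 8 of them called down, below all random lists, against 0.07 at the high dose. Between the doses Ogn (1.33 ± 0.18), Col1a2 (1.27 ± 0.07) and Ptgds (1.24 ± 0.12) were higher at the high dose, and P3h3 (-1.10 ± 0.10), Galnt16 (-0.89 ± 0.09) and Pyroxd2 (-0.70 ± 0.14) lower. Calls were 29 up and 7 down of 25335 genes at the high dose (2 in opposite directions), 24 and 40 of 26272 at the low dose (3 opposite), and 49 higher and 13 lower of 23936 between doses. With the processed signals the high-dose split was 61 up and 42 down.

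In the hippocampus the high dose raised Ccn1 (2.11 ± 0.36), Apold1 (1.97 ± 0.56), Atf3 (1.64 ± 0.54), Dusp1 (1.12 ± 0.05) and Klf4 (1.08 ± 0.47). The lowest values were those of the thyroxine carrier Ttr (-2.62 ± 0.28) and Sostdc1 (-1.35 ± 0.58), both abundant in choroid plexus, of Galnt16 (-2.13 ± 0.14), the interferon-induced membrane protein Bst2 (-0.93 ± 0.36) and P3h3 (-0.92 ± 0.36). Low-dose calls included Ccn1 (0.75 ± 0.10) and the meiotic gene Rec114 (0.65 ± 0.07) upward, and Ttr (-2.20 ± 0.18), Sostdc1 (-1.56 ± 0.42), the cartilage protein Cilp (-0.81), Ptprj (-0.79 ± 0.04) and Ogn (-0.71 ± 0.17) downward. Choroid plexus markers had medians of -0.25 and -0.37 and meningeal markers of -0.42 and -0.51 at the high and low dose, below all random lists. Between doses Atf3 (1.74 ± 0.22), Ccn1 (1.36 ± 0.47) and Apold1 (1.26 ± 0.20) were higher at the high dose, and Galnt16 (-1.55 ± 0.19) and Pyroxd2 (-0.95 ± 0.02) lower. There were 10 calls up and 15 down of 20740 genes at the high dose (4 opposite), 9 and 10 of 20477 at the low dose (12 opposite), and 8 and 5 of 19002 between doses. Median centring gave 3 up and 8 down, 5 and 3, and 14 and 31, processed signals 19 and 43 at the low dose, and an offset of 16 gave 11 and 11 between doses.

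In the amygdala Ccn1 (3.52 ± 0.40), Apold1 (2.34 ± 0.25), Atf3 (1.79 ± 0.23) and Dusp1 (1.52 ± 0.12) rose at the high dose, together with Sostdc1 (1.61 ± 0.04) and the choroid plexus transcription factor Otx2 (1.27 ± 0.14). Galnt16 stood at -2.24 ± 0.20, the vasopressin precursor Avp at -1.91 ± 0.07, the oxytocin precursor Oxt at -0.98 ± 0.18 and P3h3 at -0.72 ± 0.19. After the low dose Ccn1 (1.61 ± 0.06), the neuropeptide precursor Cartpt (0.99 ± 0.20), Apold1 (0.96 ± 0.33) and the B cell chemokine Cxcl13 (0.73 ± 0.09) were higher. Avp (-1.70 ± 0.10), Oxt (-1.06 ± 0.03), the sialyltransferase St6gal2 (-0.84 ± 0.11), RT1-CE3 (-0.81 ± 0.03) and Galnt16 (-0.78 ± 0.26) were lower. Choroid plexus markers had a median of 0.89 over 16 genes at the high dose, 12 of them called, and 0.18 at the low dose, above all random lists. The doses differed in Ccn1 (1.91 ± 0.34), Atf3 (1.64 ± 0.08), Apold1 (1.37 ± 0.07), Galnt16 (-1.46 ± 0.06), P3h3 (-1.15 ± 0.02) and Cartpt (-1.02 ± 0.03). Of 20090 genes, 50 were up and 5 down at the high dose (3 opposite), 11 and 9 of 22764 at the low dose (5 opposite), and 39 and 13 of 19418 between doses. Median centring gave 6 up and 8 down at the low dose.

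The ventral striatum showed Ccn1 (3.94 ± 0.30), Apold1 (2.18 ± 0.15), Atf3 (2.03 ± 0.29), Btg2 (1.80 ± 0.04) and Klf4 (1.35 ± 0.29) as the highest values at the high dose. Galnt16 (-1.83 ± 0.08) was lowest, followed by Cfap144 (-0.89 ± 0.23), Drc12 (-0.83 ± 0.06), the dynein chain Dynlrb2 (-0.79 ± 0.19) and Ccdc37_predicted (-0.69 ± 0.08). At the low dose Ccn1 (2.57 ± 0.30), Apold1 (1.10 ± 0.25), Btg2 (0.84 ± 0.01) and Abcg2 (0.75 ± 0.22) were higher, and the haemoglobins Hbb (-1.11 ± 0.66) and Hbb-b1 (-0.99 ± 0.24), the relaxin gene Rln1 (-0.97 ± 0.47), Trim54 (-0.84 ± 0.06) and the neuropeptide receptor Qrfpr (-0.75 ± 0.10) lower. Blood cell markers had a median of -0.41 over 8 genes there, below all random lists. Atf3 (1.79 ± 0.13), Ccn1 (1.36 ± 0.01) and Hbb (1.11 ± 0.20) were higher at the high than at the low dose, and Galnt16 (-1.19 ± 0.24), P3h3 (-1.13 ± 0.02) and Pyroxd2 (-0.80 ± 0.07) lower. The high dose gave 18 calls up and 10 down of 23743 genes (3 opposite), the low dose 9 and 8 of 24723 (8 opposite), and the doses differed in 14 upward and 13 downward of 22651. The split was 7 and 8 at the high dose with median centring, and 22 and 36 at the low dose with the processed signals.

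In the hypothalamus Pmch stood at -2.96 ± 0.02 at the high dose, the dopamine transporter Slc6a3 at least 4.32-fold lower (being not well above background in treated RNA), Galnt16 at -2.11 ± 0.02, Ttr at -2.00 ± 0.25, Sostdc1 at -1.19 and tyrosine hydroxylase, Th, at -0.96 ± 0.02. Ccn1 (1.69 ± 0.39), Sycp3l2 (at least 2.98-fold), Apold1 (1.19 ± 0.35), the intermediate filament gene Prph (1.08 ± 0.15) and Btg2 (0.89 ± 0.10) rose. The low dose gave Slc6a3 at -1.99 ± 0.13, Pmch at -1.76 ± 0.03, Th at -0.93 ± 0.01, the vesicular monoamine transporter Slc18a2 at -0.91 ± 0.26 and RT1-CE3 at -0.87 ± 0.08, with no gene with a symbol called up. Markers of midbrain dopamine and serotonin neurons had medians of -0.34 and -0.23 over 8 genes at the high and low dose, 3 called down at each and the 5 others with medians of -0.06 and -0.04. Choroid plexus markers had a median of -0.39 at the high and 0.08 at the low dose. Between the doses Haus1 (1.05 ± 0.16, whose probes disagree across regions), Ccn1 (1.04 ± 0.22) and Atf3 (0.94) were higher at the high dose, and Ttr (-2.34 ± 0.12), Sostdc1 (-1.60 ± 0.04) and Galnt16 (-1.48 ± 0.01) lower. Calls numbered 15 up and 19 down of 22418 genes at the high dose (2 opposite), 5 and 10 of 22811 at the low dose (0 opposite), and 11 and 17 of 20921 between doses. With median centring the low-dose split was 5 and 6.

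In the midbrain Ccn1 was called at the high dose with 0.65, whereas Atf3 stood at -0.10. Sycp3l2 was at least 1.67-fold higher. Col1a2 (0.86 ± 0.04), Igf2 (0.86 ± 0.19), Sgk1 (0.79 ± 0.08) and the sulphurtransferase Tst (0.77 ± 0.11) were among the highest, and Galnt16 (-1.78 ± 0.05), the thalamic kinase gene Prkcd (-0.89 ± 0.05) and Ptpn3 (-0.87 ± 0.28, probes disagree) lowest. Low-dose treatment went with higher values of the serotonin synthesis enzyme Tph2 (1.42 ± 0.38), the serotonin transporter Slc6a4 (0.90 ± 0.10), Epyc (0.99 ± 0.26) and Rsf1 (0.76 ± 0.06). Lower were the cartilage gene Cnmd (at least 2.51-fold), Prkcd (-1.17 ± 0.07), Ptpn3 (-1.03 ± 0.18, probes disagree), Hbb-b1 (-1.0 ± 0.46) and the GABA receptor subunit Gabrd (-0.75 ± 0.05). Thalamic markers had medians of -0.21 and -0.16 at the high and low dose, below all random lists, and meningeal markers medians of 0.48 and -0.26. Cilp (1.53 ± 0.25) and Cnmd, whose treated RNA was near background at the low dose, were higher at the high than at the low dose, and Galnt16 (-1.27 ± 0.20), P3h3 (-1.18 ± 0.17) and Syde2 (-0.98 ± 0.06) lower. Of 23108 genes 13 were up and 8 down at the high dose, fewer than the 62 in opposite directions. The low dose gave 11 and 17 of 23429 (25 opposite), processed signals 15 and 50 and median centring 9 and 5, and the doses differed in 51 upward and 10 downward of 21720.

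**Figure D3:**
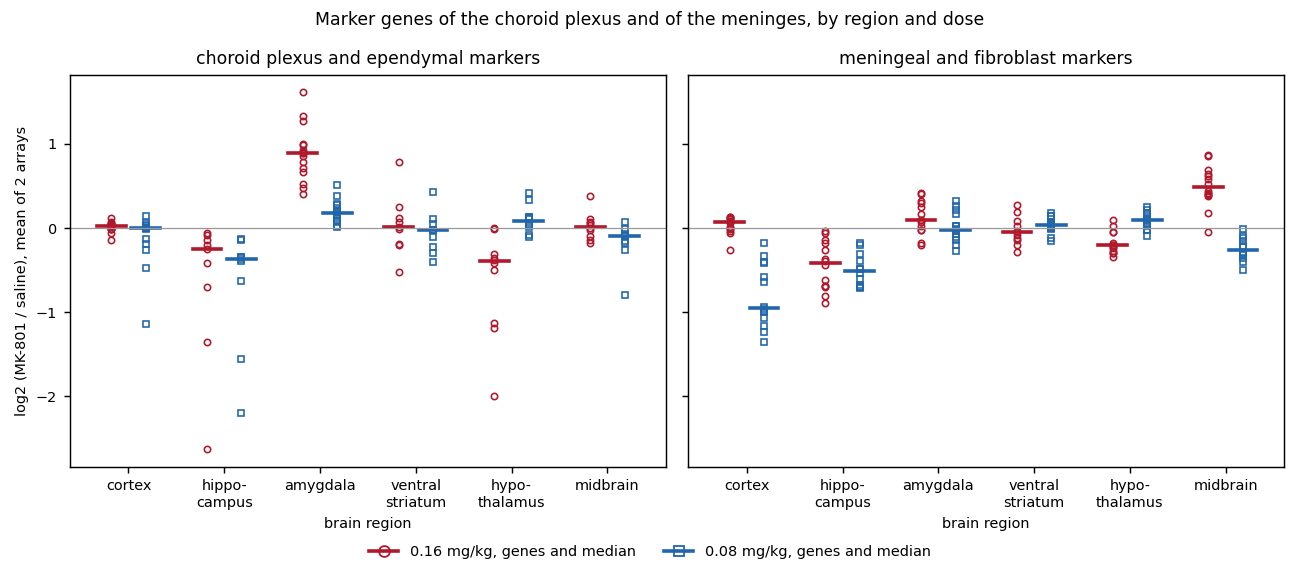
Log2 ratio of MK-801 over saline (vertical axis) of choroid plexus and ependymal markers and of meningeal and fibroblast markers by region and dose (horizontal axis), each point a gene's mean of 2 arrays and each bar the list's median. Choroid plexus markers reach a median of 0.89 in the high-dose amygdala and -0.39 in the high-dose hypothalamus, and meningeal markers -0.95 in the low-dose cortex.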

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

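Of the tests in this part, that of a remaining dye bias over all genes and those of regions with turned signs were set before their results were seen, and those of dose, of genes with opposite signs at both doses, of neighbouring genes, tissue, blood vessel cells and glucocorticoids were chosen afterwards.

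At the high dose, 8 genes moved one way on both arrays of a region and the opposite way on both arrays of another, and in each case the difference was not tested. Ttr, the thyroxine carrier of the choroid plexus, stood at 1.34 in the amygdala, -2.62 in the hippocampus and -2.00 in the hypothalamus, and Sostdc1 at 1.61, -1.35 and -1.19 in the same regions; the difference was not tested. The unnamed transcript AW142560 had values of 1.26, -0.79 and -1.03 there, and the difference was not tested. Between amygdala and hypothalamus, the potassium channel gene Kcnj13 had 0.89 and -1.13, the secretoglobin Scgb1c1 0.99 and -0.68, and the unnamed probe A_44_P889730 1.31 and -0.78; again the difference was not tested. The collagens Col1a2 (0.86 in the midbrain, -0.89 in the hippocampus) and Col3a1 (0.69 and -0.70) differed likewise, and the difference was not tested.

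Markers of choroid plexus and meninges moved as groups within single regions, in directions that differed between regions. Over the 6 combinations of these lists with a region and dose in which at least 3 members were called, 95.7% of the members that were not called (44 of 46; exact binomial interval 85.2 to 99.5) shared the sign of the called ones, which is consistent with more or less of a neighbouring tissue in the dissected piece. A drug response of these genes that is the same everywhere is argued against by the called members' values in the other regions at the same dose. Of these values 48% (71 of 148; 39.7 to 56.3) shared the sign. Per combination this share ran from 5 of 15 (meningeal, high-dose midbrain) to 9 of 14 (meningeal, low-dose hippocampus). Intervals of shares in this part count genes as independent and are too narrow where genes move together. Estimated correlations were 0.81 for choroid plexus markers at the high dose, and 0.78 and 0.86 for meningeal markers at the high and low dose. Hippocampal meningeal markers entered at both doses, which may share saline RNA. A response of such tissue in single regions, and differences between individual rats, were not tested and stay open. Avp and Oxt were lower in the amygdala and Pmch in the hypothalamus at both doses. A difference in the dissected piece was not tested for these 3 genes and stays open too. In saline RNA Avp stood at 11.07 in the amygdala and 9.14 in the hypothalamus, and Oxt at 7.96 and 9.51. In the hypothalamus 3 midbrain neuron markers were called lower at each dose, while the 5 others had medians of -0.06 and -0.04. Of these 80% (8 of 10 over both doses; 44.4 to 97.5) shared the sign, as did 52.4% of the called markers' values in other regions (11 of 21; 29.8 to 74.3), too few to decide between less of a neighbouring tissue and a response of these genes.

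Many genes shifted by small amounts with 1 sign in every measured region, 486 past the threshold at the high and 589 at the low dose. A dye effect that is equal on both arrays of a pair cancels in their mean by design. A dye effect that differs between them cannot be seen with 2 arrays: 86% kept their sign in both orientations, short of the bound of 90% set beforehand, but an effect that cancels also turns signs where shifts are small. If such a remaining bias were alike at both doses, it would give 1 sign at both, as both were hybridised in the same dye orientations. That form is argued against for the 24 genes past the threshold at both doses with opposite signs, where independent lists would share 6.37. A bias that differs between the arrays of the doses stays open for these genes too. A response that grows with dose is argued against for the same genes only by the opposite signs that selected them. For the others a response that grows with dose stays open. Outside the immediate early and glucocorticoid lists 77.8% of the low-dose genes (425 of 546) had the same sign at the high dose. A high-dose mean of that sign counted as reaching the low-dose mean if it fell short by at most 1 SE of the difference. By that measure 27.7% (151 of 546, interval 23.9 to 31.6) reached it, but selection at the low dose inflates the low-dose values. Of genes selected at the high dose 68.4% (312 of 456, interval 63.9 to 72.7) reached it by the same measure. Inherited differences between the rats may contribute and cannot be told apart from a drug response: 10 pairs of neighbouring genes with symbols shared a direction against a median of 3 and a maximum of 11 in 1000 random draws (1 draw had as many), a count narrowed after 52 pairs over all features had exceeded the random maximum of 20. The labels do not say how many rats stood behind an extract.

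At the high dose 14 of 45 immediate early genes were higher and 1 lower in treated than in saline rats, and the call of the list was lost with an estimated correlation (adjusted p = 0.467) and with fry (0.0921). At the low dose 6 of 47 were higher and 5 lower, and the list did not pass (0.46). More blood vessel cells in the treated samples are argued against, for the 14 immediate early genes that rose (median 0.684), by the endothelial and mural markers. Their median was -0.00956 at the high dose (14 genes, upper bound 0.0355, with genes counted as independent). On scan days 1, 2 and 3 it was -0.109, 0.027 and 0.0423. The 14 immediate early genes were chosen for having risen, whereas the median of their whole list was 0.06. A response that grows with dose stays open: 85.7% of those genes (12 of 14) were higher at the high than at the low dose in at least 5 of 6 regions, but their selection at the high dose favours this, and of the genes selected at the low dose 5 of 6 were, too few to decide. Glucocorticoid release stays open: the glucocorticoid list differed by a median of 0.0206 between doses (0.011 to 0.109), an interval that includes the 0.101 of the immediate early list. Differences in handling or housing between treated and saline rats were not tested. Rats were kept 3 per cage, so cage and treatment group may coincide.

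Regions agreed in sign more often than noise that is independent between regions would give, as turning the signs of regions never gave as many calls. Among the 32 arrangements the real one was the only 1 with as many calls at the high dose (507 against at most 4, with the hypothalamus turned), at the low dose (617 against at most 1, with the hippocampus turned) and between doses (386 against at most 2, with the hypothalamus turned). Turned signs do not address differences shared by all regions of the same rats. Chance differences between rats or extracts that all regions share would give the same result, so they are not excluded.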

How the results depend on the processing

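The alternatives with scan day as a block or alone were chosen after seeing the data, and all others beforehand. No called list reversed its direction under the alternatives tried on lists, nor did a called value of a named gene under those tried on named genes. Values that were not called were not judged by sign. Some of them turned on a single array, such as Junb in the high-dose hippocampus (mean 0.06, replicate 1 at -0.19). Within scan days, which were not among these, the called dose differences of meningeal markers (median 0.24) and glucocorticoid-responsive genes (0.02) had medians of -0.134 and -0.00135 on day 1, and those of oligodendrocyte markers (-0.06) a median of 0.023 on day 2; the cause was not tested. Of 415 values of genes named across regions, 412 stayed on their side of the threshold and 3 lost the call (Btg2 at the low dose). Of 779 list values, 736 stayed, 34 lost and 9 gained a call. Of 1197 values of genes named per region, 971 moved by less than the SD of the pair and 226 by more, and between doses 175 of 252 and 77. The SD of a pair includes the dye effect, which makes this a lenient bound for genes named per region. Using each array alone left 342 values within 1 SD by construction. Dim probes, with 56.8% to 89.7% of spots well above background, limit the smallest ratios that can be seen. No paired analysis was possible because the replicate number marks the dye orientation and the labels name no rat, so nothing could be paired beyond the region, within which the doses were compared.

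Counts of genes called per region are given below in the order high and low dose, for cortex, hippocampus, amygdala, ventral striatum, hypothalamus and midbrain, followed by the counts between doses for the same regions. With 1.5-fold, loess and an offset of 50 they were 36 and 64, 25 and 19, 55 and 20, 28 and 17, 34 and 15, and 21 and 28, then 62, 13, 52, 27, 28 and 61. The scanner software's processed signals gave 103 and 134, 95 and 62, 107 and 46, 116 and 58, 95 and 67, and 136 and 65, then 132, 73, 102, 96, 96 and 147; the cause was not tested. The deposited value table gave 104 and 136, 96 and 62, 107 and 47, 119 and 59, 96 and 68, and 136 and 65, then 135, 76, 103, 99, 98 and 152; it holds the same processed signals. A 2-fold threshold left 19 and 20, 7 and 4, 18 and 8, 10 and 4, 7 and 4, and 1 and 7, then 15, 4, 9, 7, 8 and 10, being stricter by construction. The array-level limma fit called 227 and 338, 202 and 363, 293 and 357, 271 and 203, 294 and 146, and 481 and 283. It has no size threshold, tests by p-value and fits a dye effect, and which of these moved the counts was not tested.

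Median centring instead of loess gave 33 in the low-dose cortex, 11 and 8 in the hippocampus, 35 in the high-dose amygdala, 15 and 8 in the ventral striatum, 17 in the high-dose hypothalamus, 7 and 14 in the midbrain and 45 between doses in the hippocampus. Across regions it gave 287 genes at the high dose and 152 between doses, and an adjusted p of 0.279 for glucocorticoid-responsive genes between doses; the cause was not tested. An offset of 16 gave 44 in the high-dose ventral striatum, 23 in the low-dose hypothalamus, 35 in the high-dose midbrain, and 22 and 43 between doses in hippocampus and hypothalamus; the cause was not tested.

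With another scaling or background setting the share of upward calls moved by over 10 points as follows. With processed signals it was 59.2% against 80.6% in the high-dose cortex (61 up, 42 down), and at the low dose 30.6% against 47.4% in the hippocampus, 37.9% against 52.9% in the ventral striatum and 23.1% against 39.3% in the midbrain. The deposited table gave 58.7% (61 and 43), 30.6% (19 and 43), 37.3% (22 and 37) and 23.1% (15 and 50). Median centring gave 27.3% against 40% in the high-dose hippocampus and 46.7% against 64.3% in the high-dose ventral striatum. At the low dose it gave 62.5% against 47.4% in the hippocampus, 42.9% against 55% in the amygdala, 45.5% against 33.3% in the hypothalamus and 64.3% against 39.3% in the midbrain. Between doses in the hippocampus the share was 31.1% with median centring and 50% at an offset of 16, against 61.5%. It also moved in 11 cases with a 2-fold threshold (0% of 1 call against 61.9% in the high-dose midbrain, 100% of 4 against 52.9% in the low-dose ventral striatum, 0% of 8 against 39.3% between doses in the hypothalamus), in 7 with the array-level fit (51.5% against 80.6% in the high-dose cortex), in 11 on single arrays (21.6% against 61.9% in the high-dose midbrain) and in 1 on scan day 3 alone (66.7% against 53.6% at the high dose across regions).

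On a single array of each pair, without replicate 1 or without replicate 2, counts ranged from 70 to 85 and 99 to 127 in the cortex, 87 to 135 and 130 to 262 in the hippocampus, 97 to 139 and 48 to 373 in the amygdala, 98 to 125 and 85 to 119 in the ventral striatum, 70 to 100 and 38 to 45 in the hypothalamus, and 344 to 476 and 97 to 337 in the midbrain. Across regions they ranged from 6499 to 7533 at the high dose, 7305 to 8342 at the low dose and 174 to 317 between doses, since the dye effect does not cancel with 1 orientation. In leave-one-out fits over regions, counts ranged from 304 to 438 at the high dose (lowest without the cortex), 388 to 569 at the low dose (lowest without the ventral striatum) and 275 to 346 between doses, with fewer regions tested.

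Scan day 1 alone gave 108, 274 and 56 genes at the high dose, low dose and between doses, scan day 2 gave 410, 141 and 245, and scan day 3 gave 198, 73 and 57, with 2 regions each. All genes called over 6 regions had the same sign in all 3 scan days. Their selection on the same region values favours this, so it does not test an effect of scan day. Scan day as a block gave 447, 423 and 350. The slide as a random block with a dye effect gave 720, 914 and 374, and the region as a random block gave 612, 747 and 373.

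With an estimated correlation, 0, 1 and 0 lists passed instead of 4, 6 and 6. Adjusted p was then 0.467 for immediate early, 0.132 for glucocorticoid-responsive and 0.135 for blood genes at the high dose, 0.431 for blood genes at the low dose, and 0.23, 0.591 and 0.23 for immediate early, glucocorticoid-responsive and blood genes between doses; the estimated correlations of these lists were 0.121 to 0.398 against the preset 0.01, which widens the test by construction. GABA genes at the high and heat shock genes at the low dose lost their calls too (0.261 and 0.431), at correlations of -0.00741 and 0.0237, so a larger correlation is not the only cause. With fry 2, 1 and 2 lists passed, with 0.0921 for immediate early genes at the high dose, 0.0501 for blood genes at the low dose and 0.243 for glucocorticoid-responsive genes between doses; fry asks a different question.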

Other observations

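In this part, the interferon-stimulated list was chosen after 6 of its kind had been seen among the decreased genes, which were left out of it, and the tests of that list and of second probes were set before their results were seen.

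The saline channels also describe how cell types differed between the dissected regions, in which slide and region cannot be told apart. Myelin and oligodendrocyte markers were highest in the midbrain (median 1.23 log2 units above the other 5 regions, 17 of 17 genes higher) and hypothalamus (0.95, 17 of 17) and lowest in the amygdala (-1.34, 0 of 17). The amygdala was instead rich in meningeal markers (1.56, 14 of 14), choroid plexus and ependymal markers (1.10, 14 of 15) and microglia markers (0.44, 17 of 17). Thalamic neuron markers were highest in the hypothalamus (2.31, 12 of 12), above the midbrain (0.21, 7 of 12). Avp, made in hypothalamic nuclei and in extended amygdala, had a higher saline level in the amygdala (11.07) than in the hypothalamus (9.14), whereas Pmch reached 13.07 in the hypothalamus and 8.31 in the amygdala. Immediate early genes were highest in the saline cortex (0.48, 40 of 46 higher).

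Of 20 class I histocompatibility genes tested at both doses, chosen as a family after some of their values were seen, 10 passed the threshold of the limma fit across regions at both. Saline RNA shared by both doses was not excluded as a source of equal signs. At the high and low dose RT1-CE2 stood at -0.39 and -0.41, RT1-A2 at -0.37 and -0.44, RT1-S3 at -0.34 and -0.44, RT1-CE16 at -0.41 and -0.65, RT1-CE3 at -0.40 and -0.74, RT1-Aw2 at -0.22 and -0.30, RT1-CE4 at -0.22 and -0.15, and RT1-Cl at -0.24 and -0.18. RT1-CE10 was instead higher, at 0.21 and 0.29, as was RT1-N1 at 0.14 and 0.20. Another 3 passed at the high dose alone, RT1-T24-4 (-0.24, against -0.01 at the low dose), RT1-CE1 (-0.18, against -0.10) and RT1-CE12 (-0.16, against -0.03), and 7 passed at neither. Signs differed between doses in 2 of these 7, RT1-CE5 (-0.03 and 0.06) and RT1-T18 (-0.09 and 0.02).

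A lower interferon response in the brains of the high-dose rats was considered as a hypothesis. In a list of other interferon-stimulated genes, 22 of 26 measured members were below 0 at the high dose with a median of -0.0888 and 6 past the threshold, led by Usp18 at -0.35 ± 0.04, Ifi44 at -0.28 ± 0.03 and Gbp2 at -0.27 ± 0.04 (camera p = 1.18e-09, or p = 0.0147 with an estimated correlation). The other probe of Usp18 stood at -0.14 at that dose. At the low dose the median was -0.0212 with 15 of 27 members below 0 and 4 past the threshold, led by Rsad2 at -0.31 ± 0.05 (camera p = 0.0041, or p = 0.0946 with an estimated correlation), and between doses it was -0.0603 with 20 of 24 below 0, 2 past the threshold downward and 1 upward (camera p = 2.59e-05, or p = 0.0282 with an estimated correlation). The one upward was Rsad2 at 0.19 ± 0.04, which goes against the hypothesis, and Ifitm3 too was lower at the low (-0.16) than at the high dose (-0.09). Most values of the list at the high dose went the way that hypothesis expects. Genes induced together can move together with the 6 first seen in the same RNA, so the list gives no independent support. Its p-values were not adjusted over lists. Whether such a difference preceded the injection in these rats cannot be read from a single time point.

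Sequence variants under single probes could also shift a gene alike in every region. For 149 pairs of gene and dose with further probes, the other probes moved by a median of 0.454 of the called probe's shift (0.353 to 0.575), between the level of under 0.25 set beforehand for variants and that of over 0.5 set for a shift of the whole transcript. The ratio was under 0.25 in 52 pairs, of which 23 had the opposite sign, and over 0.5 in 69. The test leaves this explanation open, and isoforms, cross-hybridisation and noise of dim probes were not tested.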
